A study of Mus musculus with 8 samples.

How the data were processed

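RNA from 8 mouse liver samples was made into libraries after removal of ribosomal RNA with a kit that keeps strand, per the labels' protocols. The labels name the build mm10, and the aligner, the counter and their settings are not given in the sources used here. The deposited table was a gene annotation with 1 row per gene and 11 columns, which hold the chromosome, position and strand, symbol, identifier, source, biotype and version numbers, per the file headers. It was checked column by column. The columns that hold only numbers are annotation versions, and 0 columns name a library, so expression was not analysed here. The test of shASIrs2 against control, the gene lists and the marker lists were therefore not run. They had been fixed before the data were examined. No sequencing depth or replicate error can be given from this table, and no other processed data of the series were examined.

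The groups were taken from the sample titles, with 4 control and 4 shASIrs2 libraries. From the rule for named genes fixed in advance, the part that needs only coordinates was applied: Irs2 and every gene within 100 kb of it. Starts, ends and strands were read with Python 3.11.15, counted from 1. Gaps are the bases between the ends of 2 genes, and overlaps are the bases they share. Exons, coding parts and UTRs came from GENCODE M21, an annotation of GRCm38, which is the assembly behind mm10. Of the 49585 genes, 49326 had the same identifier in GENCODE M21, and 45125 of these, or 91.48%, had identical start, end and strand there. Irs2 was compared with other protein-coding genes by the number of long noncoding genes within 100 kb, counting the lincRNA, antisense, processed-transcript, bidirectional-promoter, sense-intronic, sense-overlapping, macro lncRNA and 3′-overlapping classes. Windows of 50 and 200 kb, GENCODE M21 in place of the deposited table, and a count without pseudogenes were tried as alternatives.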

Results

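The series covers liver RNA from 12-week-old wild-type C57BL/6 mice taken after refeeding. The labels give 4 control libraries and 4 libraries titled shASIrs2, and the series title speaks of ASIrs2 suppression. Irs2 encodes insulin receptor substrate 2, an adaptor that carries the insulin signal from its receptor to the kinases downstream. The design implies 1 comparison, between the 4 shASIrs2 and the 4 control libraries. That comparison was not analysed here. The table used holds 49585 genes in 11 annotation columns, and 0 of the columns belong to a library, so no expression level, depth, fold change or test is reported for any gene. What can be described from it is the annotation around Irs2, the gene whose name is part of ASIrs2. Whether any transcript was suppressed was not checked here.

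Irs2 (ENSMUSG00000038894) was annotated as a protein-coding gene on the minus strand of chromosome 8, from 10984681 to 11008458 in mm10, a span of 23778 bp. Within 100 kb of it the table listed 9 other genes, and 0 of these were protein-coding. They were 6 lincRNA genes, 2 genes of the processed-transcript class and 1 processed pseudogene. Of the 9 neighbours, 5 lay on the strand of Irs2 and 4 on the opposite strand.

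Only 1 of the 9 neighbours overlapped Irs2. This gene, 9530052E02Rik (ENSMUSG00000096938), was a processed transcript on the plus strand from 11007850 to 11054541. It is therefore antisense to Irs2 over 609 bp at the 5′ end of Irs2, and most of its 46692 bp lie upstream of Irs2. In the GENCODE M21 annotation, exon 1 of its transcript ENSMUST00000180750.7 ran from 11007850 to 11008011. Those 162 bp lie inside the coding part of Irs2 exon 1, which runs from 11004470 to 11008430, and do not reach the 5′ UTR that follows to 11008458. Its other annotated transcript, ENSMUST00000181315.1, started at 11049578 and shared no exon with Irs2. None of the 9 neighbours carries the name ASIrs2, and the labels do not tie that name to an annotated gene. For this reason 9530052E02Rik is given here by position only and is not equated with ASIrs2.

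The nearest neighbour that did not overlap was the lincRNA gene Gm44956, on the strand of Irs2 from 10962957 to 10970814, 13866 bp beyond the 3′ end of Irs2. Gm44955, another lincRNA gene on that strand, followed at 36790 bp. On the other side of Irs2, the lincRNA gene B830042I05Rik lay on the plus strand from 11071046 to 11076881, 62587 bp from Irs2. The remaining neighbours, Gm45044, Gm45043, 4833411C07Rik, 3930402G23Rik and the pseudogene Gm45042, lay between 54583 and 93089 bp beyond the 3′ end of Irs2. These are positions of gene models and carry no information on whether any of them was transcribed in these livers.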

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

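The count of annotated genes around Irs2 depends on the window, by construction. It was 9 within 100 kb, 3 within 50 kb and 16 within 200 kb. It was 9 with GENCODE M21 in place of the deposited table and 8 with pseudogenes left out. All 4 alternatives were chosen after seeing the data. The alternatives planned for the expression comparison (other scalings, filters, tests, surrogate variables, library weights, and leaving out each library) were not run, because the table used holds annotation only. No paired analysis was possible because no values of single libraries were analysed here.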

Other observations

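In the deposited annotation, 8 long noncoding genes lay within 100 kb of Irs2. The median over the 21973 protein-coding genes was 1, and 62 of them, or 0.28%, had 8 or more, Irs2 included. This comparison was made with the 100 kb window only, and the count around Irs2 depends on the window. Gene length was not taken into account, and a longer gene has a wider window. An overlap with a long noncoding gene on the opposite strand, as between Irs2 and 9530052E02Rik, was found for 2961 protein-coding genes, or 13.48%. These are counts of gene models, chosen after the table was seen, and no explanation was tested.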
